A study of Mus musculus with 24 samples.

How the data were processed

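Gene expression was measured in mouse primary hepatocytes on Affymetrix MoGene 2.0 ST arrays. Per the labels, the cells came from male C57Bl6J mice. They received an adenovirus carrying a short hairpin RNA (shRNA) against FOXA2 or against lacZ, a bacterial gene that mouse cells lack, at a multiplicity of infection of 5. The cultures were treated for 4 h with 1 nM insulin or 100 nM glucagon, each together with the solvent DMSO or with 2 µM GW4064, a synthetic agonist of the bile acid receptor FXR (gene Nr1h4). The medium held 100 nM dexamethasone, and labelled DNA was made from 300 ng of total RNA, per the labels' protocols. The 8 groups of the resulting design held 3 arrays each, numbered by the labels as experiments 1 to 3. Per the series' design text, each experiment used hepatocytes pooled from 3 mice, technical replicates were pooled within each sample, and GeneSpring software was used. The replicates were therefore experiments, and for comparisons within 1 condition p-values measured the spread between them. For differences averaged over 4 conditions, the pairs of an experiment entered the error as separate. A difference that varies between experiments is then only partly in that error.

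The values analysed were the log2 expression values that the authors deposited, 24 columns for 41345 probe sets with 0 missing values. Their log2 scale was read from the values, which lay between 1.46 and 13.5. The array medians lay between 3.21 and 3.28, the lower quartiles between 2.66 and 2.72 and the upper quartiles between 5.17 and 5.36. The normalization and background correction behind these values are not given in the sources used here. Pairs of arrays correlated at r = 0.975 to 0.997 across the 22180 genes defined below, which are not independent replicates. Replicates of a group correlated at 0.986 to 0.994 across these genes. No pair of replicates shared more than 4 identical values over all probe sets. The number of arrays limits the precision. For a single comparison of 3 against 3 arrays, the median standard error over genes was 0.13 on the log2 scale, and 0.063 for a difference averaged over 4 conditions.

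Probe sets were named through the platform annotation. Of the 41345 probe sets, 23521 had 1 gene symbol, 1814 had several and 16010 had none. The gene numbers of 23328 of the first kind were found in the reference gene table. Where a gene had several probe sets of its own (1082 genes), that of the highest mean over all arrays was used. This gave 22180 genes. Genes on probe sets with several symbols were not tested as genes, and Slc51b, a gene of the core set and of the FXR target list fixed in advance, was left out for that reason.

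Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes). The model had 1 mean per group, all 24 arrays in the same fit and 16 residual degrees of freedom. The Benjamini-Hochberg adjustment ran over all genes tested, with a threshold of 0.05. By chance a share of 0.05 of the genes tested would have an unadjusted p under 0.05. Of the unadjusted counts given below, only those of the averaged knockdown and of hormone by knockdown lie above that share. The contrasts were glucagon minus insulin, GW4064 minus DMSO and shFOXA2 minus shlacZ within fixed levels of the other factors, the same differences averaged over the 4 conditions of the other 2 factors, and 4 interactions. A difference of 1.5-fold was used to count larger changes. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

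The experiment numbers paired the arrays. Deviations from the group means correlated between arrays of the same experiment in all 84 pairs, at r = 0.374 to 0.698 with a median of 0.474. For each of the 24 arrays, the best correlated array of another group was from the same experiment. An alternative fit therefore had the experiment as a block, with 14 residual degrees of freedom. Because the design is balanced, the block left every log2 difference as it was and changed only its error. With the block, the count of hormone-responsive genes in control cells was 2481 instead of 1039.

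Gene lists were fixed before the data were examined. They covered gluconeogenesis, early cAMP and CREB targets, amino acid catabolism and the urea cycle, fatty acid oxidation and ketogenesis, lipogenesis and insulin targets, cholesterol synthesis, FXR targets, bile acid synthesis and uptake, liver transcription factors, plasma proteins, the ER stress and amino acid response, acute phase and inflammation, xenobiotic metabolism, the interferon response and the cell cycle. Marker lists covered macrophages including Kupffer cells, stellate cells, endothelial cells, cholangiocytes, lymphocytes and erythroid cells. Of 266 listed genes, 233 were tested, and 0 of the erythroid markers. The other 20 lists were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists of a contrast. Camera with an estimated correlation and fry were alternatives. The lists overlap. Ppargc1a is on the gluconeogenesis and cAMP lists, Got1 on the gluconeogenesis and amino acid lists, and Tat on the cAMP and amino acid lists. The calls of these lists are therefore not independent. Lists of NRF2 targets (9 genes tested) and NF-kB targets (10 genes tested) were added after the data had been seen.

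The genes named in the text were chosen by a rule. For each contrast it took the 6 largest rises and the 6 largest falls among genes that passed the threshold with the same sign in all 3 experiments. It also took a core set whatever its result (Foxa2, Nr1h4, Pck1, G6pc, Ppargc1a, Pklr, Nr0b2, Abcb11, Cyp7a1, Cyp8b1 and Fbp1), and, for each list with a passing member, the 2 to 4 members of smallest adjusted p. Genes outside this rule are said to be chosen after their values were seen.

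Alternatives planned in advance were the block, quantile normalization, centring each array on its median, leaving out the 30% of genes with the lowest means, fitting only the groups compared, eBayes with trend and robust settings, the mean of a gene's probe sets, all probe sets, array weights, and leaving out each array or experiment in turn. The block combined with a left-out array or experiment, with the filter on dim genes or with all probe sets was added after the data had been seen.

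The tests were checked on simulated values with the spread of the real arrays over 22180 genes, 50 genes changed at each size. For glucagon against insulin in control cells, 34% of genes changed by 0.5 on the log2 scale were recovered without the block and 66% with it, and 86% and 94% of those changed by 1. For the averaged knockdown, 42% of changes of 0.25 and 84% of changes of 0.5 were recovered without the block, and 66% and 96% with it. For the interaction of GW4064 with the hormone, 10% of changes of 0.5 and 62% of changes of 1 were recovered without the block. A simulated list of 15 genes shifted by 0.3 gave a camera p of 4.6e-15, and 3 of 100 unchanged lists had p under 0.05. The random part of each simulated gene was drawn independently, whereas genes of a real list can be correlated. The 3 of 100 therefore does not give the error rate of camera on the real lists. Each simulated change was also the same in all experiments. For a real difference that varies between experiments, the shares recovered may be lower.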

Results

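The 24 arrays measured the transcripts of mouse hepatocytes in 8 groups of 3, which crossed a hairpin against FOXA2 or lacZ (shFOXA2, shlacZ) with insulin or glucagon and with DMSO or GW4064. Insulin is the hormone of the fed state and glucagon that of fasting. No group lacked both, so a rise under glucagon cannot be told from a fall under insulin, and rises and falls below are those of glucagon against insulin. FOXA2 is a liver transcription factor and FXR, which GW4064 activates, a nuclear receptor for bile acids. Going by the title of the series, the comparisons ask how glucagon signalling, FXR and FOXA2 act together on gluconeogenic genes. Levels are on a log2 scale and are given as mean ± SD with n = 3 arrays per group, 1 per experiment, and differences are log2 differences with their standard error (SE). The median level of all probe sets was 3.25, and levels near it are close to the floor of the arrays.

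Foxa2, the target of the hairpin, was lower in the shFOXA2 array than in its shlacZ partner in 12 of 12 pairs of the same experiment and treatment. Under insulin and DMSO its level was 6.27 ± 0.038 with shlacZ and 5.77 ± 0.28 with shFOXA2. Under glucagon and DMSO it was 7.47 ± 0.24 and 7.02 ± 0.19, under insulin and GW4064 6.14 ± 0.072 and 5.76 ± 0.20, and under glucagon and GW4064 7.31 ± 0.19 and 6.90 ± 0.12. Averaged over the 4 conditions the difference was -0.43 (SE 0.072, -25.9%), with a limma adjusted p of 0.0613, and 0.0194 with the experiment as a block. Within single conditions Foxa2 did not pass, with adjusted p from 0.968 to 1.00, and from 0.501 to 0.608 with the block. The SE of the averaged difference takes the pairs of an experiment as separate. The depth of the knockdown differed between experiments. It was -0.51 in experiment 1 (-30.0%), -0.66 in experiment 2 (-36.8%) and -0.12 in experiment 3 (-8.07%, 4 pairs each), where the pairs lay between -0.23 and -0.03. Cells with the hairpin are called knockdown cells below, those of experiment 3 included. Without experiment 3 the difference was -0.59 with an adjusted p of 0.00805. Without experiment 1 it was -0.39 and without experiment 2 -0.32, with adjusted p of 0.858 and 0.9998.

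**Figure D1:**
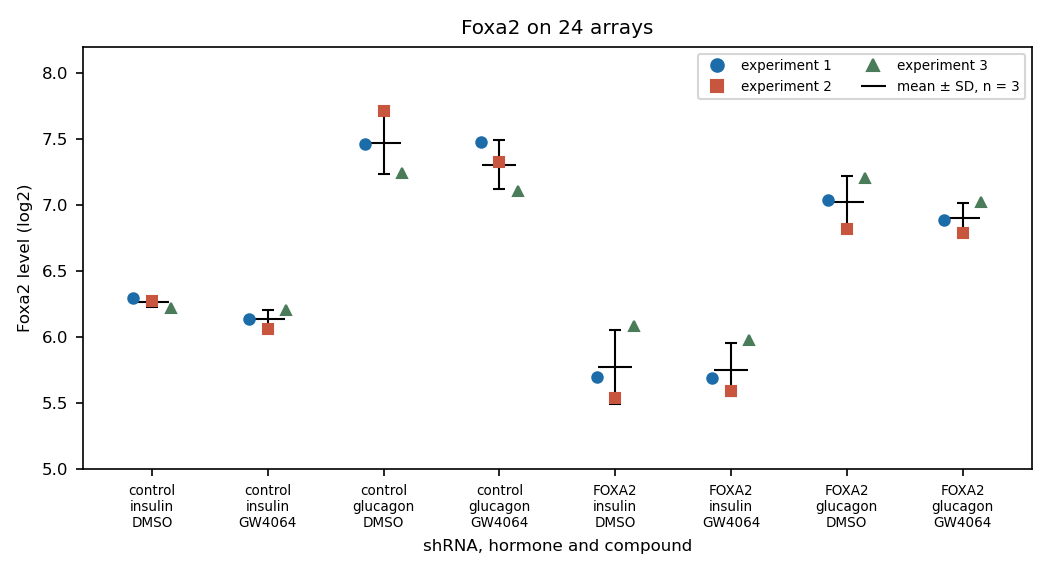
Foxa2 log2 level on each of the 24 arrays, by group, with points coloured by experiment and the mean ± SD of 3 arrays. The group means of the control (shlacZ) arrays lie between 6.14 and 7.47 and those of the shFOXA2 arrays between 5.76 and 7.02, with the smallest separation in experiment 3.

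Glucagon changed the control hepatocytes widely against insulin. The gluconeogenic enzyme genes Pck1 and G6pc rose from 3.61 ± 0.14 to 9.66 ± 0.66 and from 3.09 ± 0.30 to 8.48 ± 0.39, differences of 6.06 (SE 0.59, adjusted p = 1.9e-06) and 5.39 (SE 0.46, adjusted p = 3.3e-07). The insulin levels of both were close to the floor, so their folds of 66.6 and 42.0 are set against near-background signal. Nr4a3, an orphan nuclear receptor gene induced by cAMP, rose from 2.76 ± 0.23 to 7.97 ± 0.060. Ppargc1a, a coactivator of fasting genes, rose from 3.39 ± 0.47 to 6.77 ± 0.74. Under insulin Nr4a3 lay between 2.45 and 3.00 and Ppargc1a between 2.61 and 3.91 on all arrays, so their differences too are set against near-background signal. The immediate-early gene Egr1 fell from 7.35 ± 0.34 to 4.06 ± 0.11 (difference -3.30, SE 0.20, adjusted p = 4.3e-09).

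In all, 379 genes were higher and 660 lower under glucagon (limma, shlacZ and DMSO), and 1038 of these 1039 had the same sign in all 3 experiments. They were called on these same experiments, so that agreement is no separate support. Over all genes the share was 43.7%, against 25% by chance. Of the genes called, 249 rose and 369 fell by over 1.5-fold. The other largest rises were those of Aass, an enzyme of lysine breakdown (3.46), and Gm15998 (3.32). The other largest falls were those of Map2k3os (-3.29), Rrad (-2.87), the growth factor gene Hbegf (-2.66), Phlda1 (-2.63) and Hmga2-ps1 (-2.62). With the block, 1033 genes were higher and 1448 lower. Fewer genes passed without experiment 1 (297) or experiment 2 (313), whereas 982 passed without experiment 3. Without the insulin array of experiment 1, the insulin array of experiment 2 or the glucagon array of experiment 2, 691, 629 and 613 passed. With each array centred on its median, 292 genes were higher and 872 lower.

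Of 10 gluconeogenesis genes measured, 5 rose, 0 fell and 5 did not pass, and 6 rose when adjusted over the list alone (median difference 1.03, camera adjusted p = 1.0e-11). Besides Pck1, G6pc and Ppargc1a, these were the transaminase genes Got1 (1.71) and Gpt2 (1.17). Fbp1, which encodes fructose-1,6-bisphosphatase, differed by 0.88 with an adjusted p of 0.260, and 0.00121 with the block. Of 15 early cAMP and CREB targets, 7 rose, 1 fell and 7 did not pass, with 8 rises and 1 fall adjusted over the list alone (median 0.56, adjusted p = 1.5e-11). The kinase gene Sik1 rose by 2.33, the orphan receptor gene Nr4a1 by 1.93 and Igfbp1, a liver-secreted binding protein of insulin-like growth factors, by 1.52. The member that fell was Junb, a subunit of the AP-1 factor named after its values were seen, at -1.26. Of 18 genes of amino acid catabolism and the urea cycle, 4 rose, 0 fell and 14 did not pass, and 7 rose adjusted over the list alone (median 0.58, adjusted p = 1.1e-08). These included tyrosine aminotransferase (Tat, 3.07), the arginine transporter gene Slc7a2 (2.71) and the mitochondrial ornithine carrier gene Slc25a15 (2.66).

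Liver transcription factors were also higher under glucagon. Of 15 measured, 6 rose, 0 fell and 9 did not pass, and 9 rose adjusted over the list alone (median 0.39, adjusted p = 2.2e-06). Foxa1 rose by 1.26, Foxa2 by 1.21, Cebpa by 0.83 and Foxo1 by 0.73. Of 15 plasma protein genes 0 passed singly in limma, also adjusted over the list alone, while the list had a median of 0.20 (adjusted p = 0.00217). In the ER stress and amino acid response, 0 of 13 genes rose, 3 fell and 10 did not pass, 3 also adjusted over the list alone (median -0.21, adjusted p = 0.00293). They were the stress-induced factors Atf3 (-1.95) and Ddit3 (-1.24) and Sesn2 (-1.0), a sensor of leucine. This list's call was lost at an adjusted p = 0.286 with an estimated correlation, whereas the calls of the other 5 lists held, with adjusted p from 3.1e-05 to 0.0345.

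**Figure D2:**
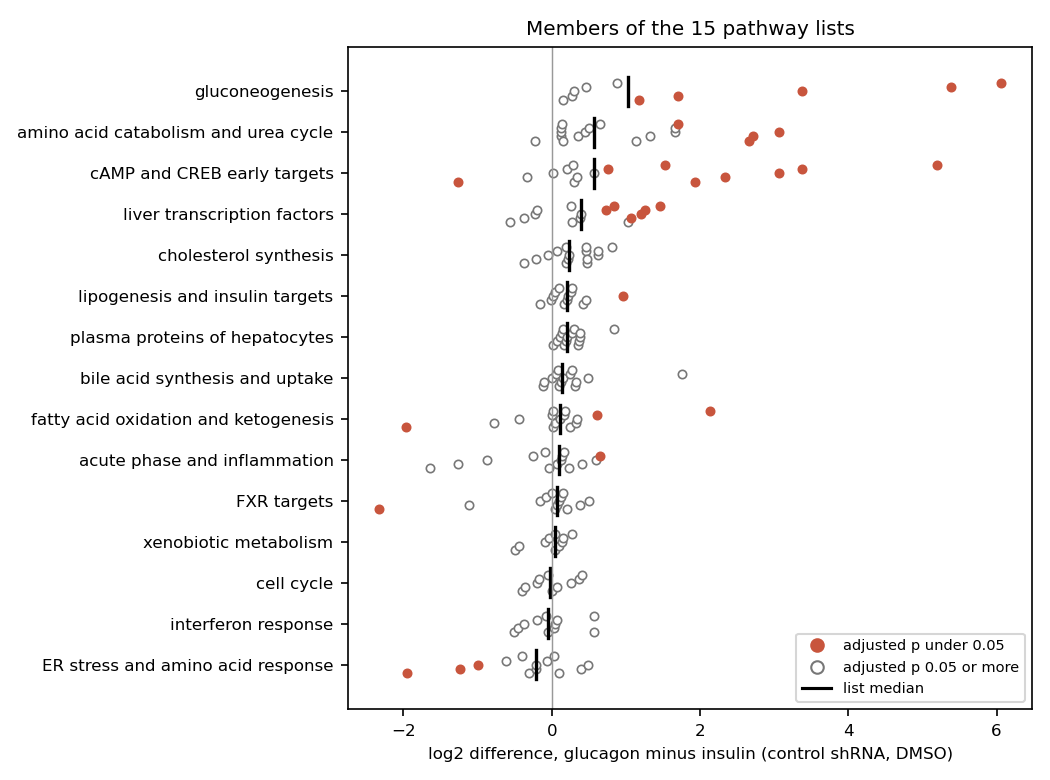
Log2 difference, glucagon minus insulin, for the members of the 15 pathway lists in control (shlacZ) cells with DMSO, filled points having an adjusted p under 0.05 and black bars marking list medians. The medians were 1.03 for gluconeogenesis, 0.56 for early cAMP and CREB targets and -0.21 for the ER stress and amino acid response.

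Genes of fatty acid oxidation changed in both directions. Of 15 genes of fatty acid oxidation and ketogenesis, 2 rose, 1 fell and 12 did not pass, and 5 rose and 2 fell adjusted over the list alone (median 0.11, adjusted p = 0.185). Cpt1a, which admits fatty acids to mitochondria, rose by 2.13 from 8.11 ± 0.18 to 10.2 ± 0.11, the nuclear receptor gene Ppara rose by 0.61, and Angptl4, an inhibitor of lipoprotein lipase, was at -1.96. In lipogenesis, 1 of 13 genes rose (Gpam, 0.96), 0 fell and 12 did not pass, with 2 rises adjusted over the list alone. The list had an adjusted p of 0.0835, and 0.00472 with the block. Its median level was 8.22 under insulin and 8.48 under glucagon. For cholesterol synthesis 0 of 15 genes passed in limma, with 3 rises and 1 fall adjusted over the list alone (median 0.23, adjusted p = 0.0835, with the block 6.6e-04). For bile acid synthesis and uptake 0 of 14 passed, also adjusted over the list alone (median 0.14, adjusted p = 0.0835, with the block 0.0217). With the block and an estimated correlation the calls of lipogenesis and cholesterol synthesis held (adjusted p = 0.0215 and 0.00693), whereas those of the bile acid, plasma protein and ER stress lists were lost (0.115 each).

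Of 13 FXR targets, 0 rose, 1 fell and 12 did not pass, with 1 rise and 1 fall adjusted over the list alone. The list had a median of 0.07, a mean of -0.16 and an adjusted p of 0.992. The fall was that of Osgin1, an oxidative stress-induced growth inhibitor gene (-2.33). Abcb11, the bile salt export pump gene, was at -1.11 (adjusted p = 0.155, with the block 1.9e-05) and Nr1h4, which encodes FXR itself, at -0.56 (adjusted p = 0.324). The repressor gene Nr0b2 was at 0.12, the bile acid synthesis genes Cyp7a1 and Cyp8b1 at 0.15 and 0.32, and the pyruvate kinase gene Pklr at 0.02, and none of these passed. Nr0b2, Cyp7a1 and Cyp8b1 lay near the floor. Of 14 acute phase genes, 1 rose (Socs3, 0.65), 0 fell and 13 did not pass, with 1 rise adjusted over the list alone (median 0.10, adjusted p = 0.789). None of 10 xenobiotic, 11 interferon and 10 cell cycle genes passed in limma, also adjusted over each list alone, with medians of 0.04, -0.05 and -0.02 and adjusted p of 0.888, 0.651 and 0.954.

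No marker of other cell types passed singly in limma with the hormone in control cells. Median levels under insulin and DMSO were 2.86 for macrophages, 2.92 for stellate cells, 4.79 for endothelial cells, 4.04 for cholangiocytes and 2.75 for lymphocytes, the first 2 and the last of them near the floor. The median differences under glucagon were 0.06, 0.09, 0.03, -0.27 and -0.06, with camera adjusted p of 0.456, 0.651, 0.561, 0.228 and 0.888.

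In cells with the hairpin against FOXA2, glucagon again raised Pck1 (5.92, SE 0.59), Nr4a3 (5.67, SE 0.16), G6pc (5.07, SE 0.46) and Ppargc1a (4.18, SE 0.55), with adjusted p of 2.2e-06, 8.3e-15, 9.0e-07 and 6.1e-05, again from insulin levels close to the floor. Pck1 went from 3.44 ± 0.12 under insulin to 9.36 ± 1.0 under glucagon. The next largest rises were those of Gm15998 (3.49) and the phospholyase gene Etnppl (3.36). Among the largest falls were Rrad (-3.61), Egr1 (-3.40), the cytokine and chemokine genes Cxcl2 (-3.19), Il23a (-3.09) and Cxcl1 (-3.03), and Csf1 (-3.00), a growth factor gene for macrophages. The falls of the last 4 were between -3.42 and -2.49 in experiments 1 and 2, whereas in experiment 3 they rest on 2 arrays that stood apart from the others of that experiment in NF-kB targets. Foxa2 itself rose by 1.25. Its level under glucagon with the hairpin lay 0.76 above that of control cells under insulin (adjusted p = 0.00281, 3 of 3 experiments).

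In these cells 470 genes were higher and 592 lower, and 325 and 369 of them by over 1.5-fold. All of those called had the same sign in 3 experiments, against 37.5% of all genes. With the block 1179 genes were higher and 1321 lower. The count was 362 without experiment 1, 363 without experiment 2, 913 without experiment 3 and 698 without the insulin array of experiment 1. Of the genes called, 254 were higher and 401 lower under glucagon with either hairpin, and 0 went opposite ways. Independent lists would share 8.03 and 17.6, counted over all genes, those near the floor included. The 2 comparisons share no arrays, but they come from the same 3 experiments and cell pools. Across all genes, which are not independent replicates, their differences correlated at r = 0.770.

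**Figure D3:**
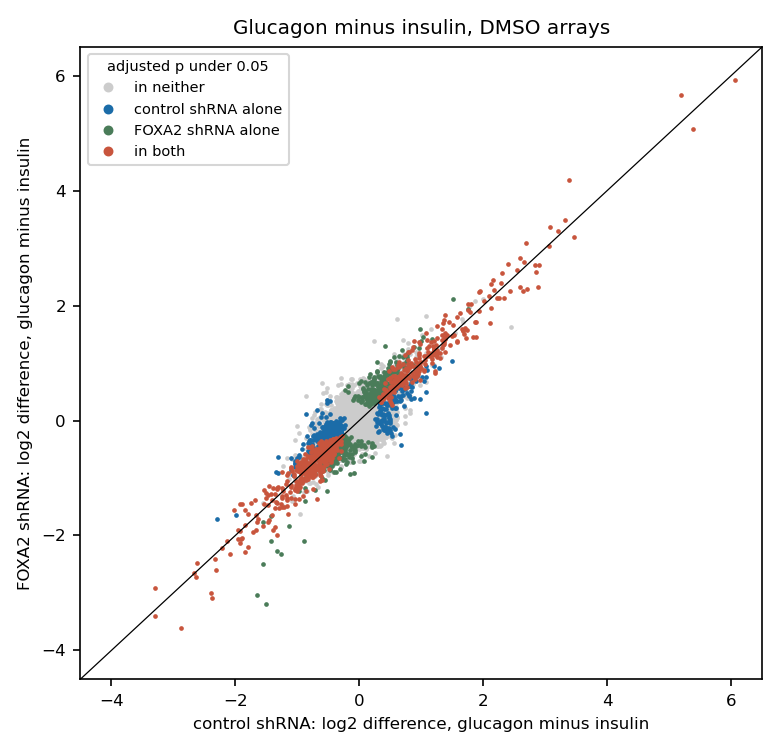
Log2 difference, glucagon minus insulin with DMSO, in control (shlacZ) cells on the horizontal axis and in FOXA2 shRNA cells on the vertical axis, 1 point per gene. Across all genes r was 0.770, and no gene was called in opposite directions.

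The gene groups of the knockdown cells were tested in the same way. Of 10 gluconeogenesis genes 5 rose, 0 fell and 5 did not pass, with 7 rises adjusted over the list alone (median 1.01, camera adjusted p = 3.8e-12). Of 15 early cAMP and CREB targets 8 rose, 1 fell and 6 did not pass, with 9 rises and 1 fall adjusted over the list alone (median 0.75, adjusted p = 4.1e-13). Of 18 amino acid and urea cycle genes 4 rose, 0 fell and 14 did not pass, with 5 rises adjusted over the list alone (median 0.63, adjusted p = 2.5e-08). Of 15 liver transcription factors 5 rose, 0 fell and 10 did not pass, with 7 rises adjusted over the list alone (median 0.37, adjusted p = 4.6e-07), among them Onecut1 at 1.45 and Foxa1 at 1.19. These 4 calls held with an estimated correlation, at adjusted p from 1.2e-05 to 0.0441. Of 13 ER stress genes 0 rose, 5 fell and 8 did not pass, also adjusted over the list alone (median -0.28, adjusted p = 0.00186), Atf3 at -2.07 and Trib3 at -0.90 among them. Its call was lost at an adjusted p = 0.311 with an estimated correlation.

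Other lists in the knockdown cells were not called. Of 14 acute phase genes 0 rose, 3 fell and 11 did not pass, also adjusted over the list alone. They were the adhesion molecule gene Icam1 (-2.32) and the chemokine genes Cxcl1 and Ccl2 (-1.40). The falls of Cxcl1 and Ccl2 passed in 11 of 21 alternatives, with adjusted p up to 0.341 and 0.281, and that of Icam1 in 19. The list had a median of -0.12 and an adjusted p of 0.115. Of 11 interferon genes 1 fell, Cxcl10 at -1.22. Of 15 genes of fatty acid oxidation 2 rose and 1 fell (median 0.20, adjusted p = 0.115). Of 13 lipogenesis genes 1 rose (0.257), and the list's median level was 8.40 under insulin and 8.37 under glucagon. Of 13 FXR targets 1 fell (median 0.10, mean -0.15, 0.713). Of 14 bile acid genes 2 rose, the organic anion transporter gene Slco1a4 (1.94) and Cyp7b1 (0.43), which passed in 10 and 7 of 21 alternatives, with adjusted p up to 0.248 and 0.482. The plasma protein list had an adjusted p of 0.191, and 0.0398 with the block. The cholesterol synthesis list had 0.249, and 0.0234 with the block. With the block and an estimated correlation the first was lost (adjusted p = 0.447) and the second held (0.0486). Fbp1 was at 0.95 (adjusted p = 0.227, with the block 5.5e-04) and Abcb11 at -0.93 (adjusted p = 0.277, with the block 1.4e-04).

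The test of whether the hairpin changed the hormone response passed for 0 genes in limma, without and with the block, with 1144 genes at an unadjusted p under 0.05. The difference between the responses was -0.14 for Pck1 (SE 0.83), -0.32 for G6pc (SE 0.65), 0.80 for Ppargc1a (SE 0.78), 0.07 for Fbp1 (SE 0.55) and 0.04 for Foxa2 (SE 0.20). None of the 20 lists was called. With the block, the acute phase list was at -0.30 with an adjusted p of 0.0457 (0.0836 without it), and an adjusted p = 0.879 with the block and an estimated correlation.

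Averaged over both hairpins and both DMSO and GW4064, glucagon raised 1636 genes and lowered 1964, of which 384 and 420 by over 1.5-fold. Of those called, 3564 had the same sign in all experiments, against 46.6% of all genes. With the block the counts were 2653 and 2801. They fell to 2018 in total without experiment 1 and 2216 without experiment 2. Without experiment 3, on as many arrays, 3610 passed. In this average Fbp1 rose by 1.22 (SE 0.19, adjusted p = 1.0e-04) and Hnf4a, a master regulator of hepatocyte identity, by 0.97. Abcb11 fell by 0.85 on the log2 scale (SE 0.20, adjusted p = 0.00534). Nr1h4 fell by 0.48 (adjusted p = 0.0184), at -0.54, 0.02 and -0.91 in experiments 1 to 3. Pklr was at -0.16 (adjusted p = 0.566, with the block 0.0235).

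In the averaged response 7 of 20 lists were called. Gluconeogenesis had 7 rises and 0 falls of 10, early cAMP and CREB targets 10 and 1 of 15, and amino acid and urea cycle genes 8 and 0 of 18. Adjusted over the list alone these were 7 and 0, 11 and 2, and 12 and 1. Liver transcription factors had 8 rises and 1 fall of 15, or 11 and 1 adjusted over the list alone, and plasma proteins 5 and 0 of 15, or 7 and 0 adjusted over the list alone. The calls of these 5 lists held with an estimated correlation. The fibrinogen gene Fga rose by 0.89 and Fgb by 0.43, and transthyretin (Ttr) by 0.27. Of 13 ER stress genes 0 rose and 7 fell, or 1 and 7 adjusted over the list alone (adjusted p = 5.9e-04), with an adjusted p = 0.16 with an estimated correlation. Cholesterol synthesis had 6 rises and 2 falls of 15, or 7 and 2 adjusted over the list alone (median 0.30, adjusted p = 0.0392), with an adjusted p = 0.666 with an estimated correlation. Sqle rose by 0.45 and Stard4 by 0.61, whereas Msmo1 was at -0.32 and Sc5d at -0.20, the last 2 being enzymes of late sterol synthesis.

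The other lists of the averaged response were not called. With the block, lipogenesis (adjusted p = 0.0531, with the block 0.00684), bile acid synthesis and uptake (0.0704, with the block 0.0254) and cholangiocyte markers (median -0.31, 0.0719, with the block 0.0343) also passed. With the block and an estimated correlation lipogenesis and cholesterol synthesis held (adjusted p = 0.0227 and 0.00407), whereas the bile acid, cholangiocyte, plasma protein and ER stress lists did not pass (0.123, 0.136, 0.123 and 0.0900). The cholangiocyte median was led by Sox9 (-1.20), a duct cell factor that fell by 2.07, 1.29 and 0.23 in experiments 1 to 3. Dcn, on the stellate cell and fibroblast list, also passed singly in limma in this average. Of the FXR targets, the proteoglycan gene Sdc1 rose by 0.48 and the exporter gene Abcc2 by 0.34, passing in 20 of 38 alternatives (adjusted p up to 0.284), whereas Osgin1 fell by 2.06 and Abcb11 was named above, and the list had a median of 0.07 and a mean of -0.10 (adjusted p = 0.716). Of 15 genes of fatty acid oxidation 4 rose and 2 fell (0.142). The acute phase list had 1 rise and 3 falls of 14, a median of 0.05 and a mean of -0.26 (0.775). The inflammatory genes differed between experiments. Cxcl1 was at -3.06, -2.73 and -0.14, Icam1 at -2.38, -1.82 and -0.51, and Ccl2 at -1.50, -1.40 and -0.09 in experiments 1 to 3. The macrophage marker median was at 0.02 in the same comparison.

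The hairpin against FOXA2 left few genes changed. Averaged over the 4 conditions, Csnk2a1, which encodes the catalytic subunit of casein kinase 2, fell by 0.30 (SE 0.034, adjusted p = 7.9e-04), at -0.31, -0.34 and -0.25 in experiments 1 to 3. Uxs1, which makes UDP-xylose, fell by 0.39 (SE 0.058, adjusted p = 0.0199), at -0.46, -0.40 and -0.31. These were the only 2 genes that passed in limma, and 1376 had an unadjusted p under 0.05. Under insulin and DMSO alone, Csnk2a1 was the only gene called, from 9.78 ± 0.072 to 9.32 ± 0.023 (difference -0.46, SE 0.068, adjusted p = 0.0368). Its adjusted p was 0.0693 with the block, and 0 genes passed without any 1 of the 6 arrays. Under glucagon and DMSO 0 genes passed in limma, with and without the block, and 939 had an unadjusted p under 0.05.

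With the block, 6 genes were higher and 11 lower in the averaged knockdown, Foxa2 among the latter. Chosen after their values were seen, the insulin-like growth factor binding protein gene Igfbp3 was at -0.56 (adjusted p = 0.874, with the block 0.0205) and the telomerase RNA gene Terc at 0.42 (0.738, with the block 0.0194). The count without the block was 0 without experiment 1 or experiment 2 and 1, Foxa2, without experiment 3, and between 1 and 4 without any single array. The gluconeogenic genes did not pass. Pck1 differed by -0.05 (SE 0.30), G6pc by 0.15 (SE 0.23), Ppargc1a by 0.11 (SE 0.27) and Fbp1 by 0.02 (SE 0.19), and Nr1h4 by 0.17 (SE 0.14). The list medians were 0.02 for gluconeogenesis, 0.04 for FXR targets, -0.01 for bile acid genes and 0.05 for liver transcription factors, of which 1 fell adjusted over the list alone, Foxa2. No list was called in limma's camera.

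With the block, camera called a few lists in the knockdown comparisons. The cell cycle list was at 0.14 in the average (adjusted p = 0.429, with the block 0.00389) and at 0.19 under insulin and DMSO (0.878, with the block 0.0429), and the interferon list at 0.23 under insulin (0.333, with the block 0.0429). Under glucagon the plasma protein list was at -0.12 and the acute phase list at -0.15, both at an adjusted p of 0.141, and 0.00779 with the block. All 5 calls were lost with the block and an estimated correlation, at adjusted p from 0.555 to 0.946. The markers of other cell types had median differences between -0.04 and 0.05 in the averaged knockdown.

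GW4064 raised 2 genes when averaged over hormone and hairpin. Mybl1, a transcription factor gene of the Myb family, rose by 1.02 (SE 0.15, adjusted p = 0.0337), and was higher in 12 of 12 pairs. In control cells it went from 5.43 ± 0.32 to 6.34 ± 0.50 under insulin and from 5.05 ± 0.35 to 6.15 ± 0.59 under glucagon. Nr0b2, which encodes the repressor SHP and is a classical FXR target, rose by 0.53 (SE 0.081, adjusted p = 0.0337) in 11 of 12 pairs. Its group means lay between 2.79 and 3.52, around the floor of the arrays. Osgin1, chosen after its values were seen, differed by 0.82 (SE 0.25) and was higher in 12 of 12 pairs, with an adjusted p of 1.00, and 7.3e-07 with the block. It was the only further gene called with the block, and 766 genes had an unadjusted p under 0.05 without it. By experiment the differences were 1.28, 0.95 and 0.84 for Mybl1, 0.66, 0.55 and 0.36 for Nr0b2, and 0.83, 0.91 and 0.72 for Osgin1.

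**Figure D4:**
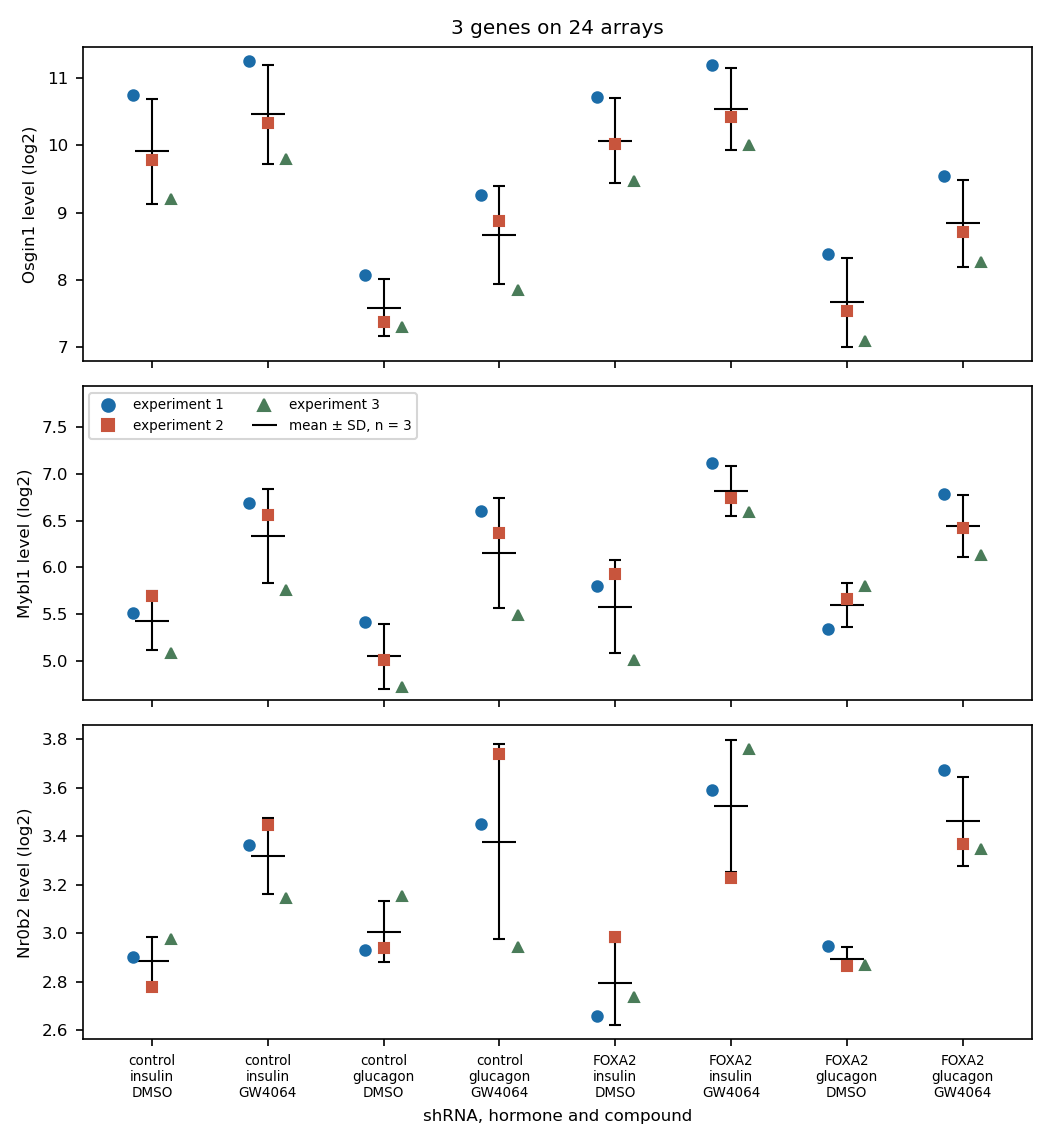
Log2 levels of Mybl1, Nr0b2 and Osgin1 with DMSO and with GW4064 in each hormone and hairpin group, with points per array coloured by experiment and the mean ± SD of 3 arrays. Mean Osgin1 with GW4064 under glucagon was 8.66 in control cells and 8.84 in FOXA2 shRNA cells, against 7.58 and 7.67 with DMSO.

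The calls of Mybl1 and Nr0b2 were lost without experiment 1 or experiment 2, when 0 genes passed in limma for the average, at differences of 0.89 and 1.06 for Mybl1 and 0.46 and 0.51 for Nr0b2. With the block, Mybl1 (adjusted p = 0.0346 and 0.0319) and Osgin1 (0.00679 and 0.00400) passed in both cases and Nr0b2 in neither (0.775 and 0.221), and 8 genes passed without experiment 3, these 3 among them. Without the block, Mybl1 and Nr0b2 passed without experiment 3 (adjusted p = 9.6e-04 and 0.0406), among 3 genes in all, whereas leaving out any single array gave between 0 and 2. Within single conditions 0 genes passed. The counts at an unadjusted p under 0.05 were 647 and 842 for control cells under insulin and glucagon and 495 and 819 for knockdown cells. With the block, Osgin1 alone passed under glucagon, at 1.08 in control cells (adjusted p = 1.00, with the block 7.9e-04) and 1.17 in knockdown cells (adjusted p = 1.00, with the block 2.2e-04).

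The gluconeogenic genes did not pass with GW4064. On average Pck1 differed by 0.07 (SE 0.30), G6pc by -0.09 (SE 0.23), Ppargc1a by 0.00 (SE 0.27) and Fbp1 by 0.40 (SE 0.19). Under glucagon the Fbp1 difference was 0.56 in control cells and 0.86 in knockdown cells (SE 0.39 each), with an adjusted p of 1.00 in both (with the block 0.584 and 0.309, SE 0.17 each). Fbp1 was higher with GW4064 in 6 of 6 glucagon pairs, by 0.20 to 1.18, and averaged over the hairpins its difference under glucagon was 0.71 (SE 0.28, adjusted p = 1.00, with the block SE 0.12 and adjusted p = 0.0614). Abcb11 was also higher in 6 of 6 glucagon pairs, by 0.22 to 0.66. On average Abcb11 differed by 0.20 (SE 0.20), Nr1h4 by -0.21 (SE 0.14), Cyp7a1 by -0.00 (SE 0.044), Cyp8b1 by 0.04 (SE 0.085), Pklr by 0.01 (SE 0.14) and Foxa2 by -0.11 (SE 0.072). Cyp7a1 lay between 2.44 and 2.84 and Cyp8b1 between 2.67 and 3.51 on all arrays, at the floor, so a fall of either would not have been seen. Of 13 FXR targets 1 rose, 0 fell and 12 did not pass, with 2 rises adjusted over the list alone (median 0.07, camera adjusted p = 0.0236). This call was lost at an adjusted p = 0.337 with an estimated correlation. With the block 1 list was called for this average, and 0 with the block and an estimated correlation. The gluconeogenesis list had a median of -0.01 and an adjusted p of 0.954. Medians of markers of other cell types lay between -0.01 and 0.05.

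Within single conditions, the interferon list was called for knockdown cells under insulin, with a median of -0.26 (adjusted p = 0.0185, and adjusted p = 0.693 with an estimated correlation), although 0 of its 11 genes passed. With the block the FXR target list was also called in 3 conditions. Its medians were 0.05 in control cells under glucagon (adjusted p = 0.459, with the block 0.0309), 0.09 in knockdown cells under insulin (0.137, with the block 0.00517) and 0.23 in knockdown cells under glucagon (0.110, with the block 6.5e-05). In control cells under glucagon the block also called the amino acid list (-0.14, 0.439, with the block 0.0226), the bile acid list (-0.11, 0.333, with the block 0.0309), the interferon list (0.18, 0.0536, with the block 0.0119) and the lymphocyte markers (0.08, 0.0536, with the block 0.0309). In knockdown cells under glucagon it called the plasma proteins (0.12, 0.607, with the block 0.0408). None of these passed with the block and an estimated correlation.

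Interactions tested whether GW4064 acted differently by hormone or hairpin. For GW4064 by hormone in control cells 0 genes passed in limma, with and without the block, and 618 had an unadjusted p under 0.05. The interaction was 0.47 for Fbp1 (SE 0.55), 0.47 for Abcb11 (SE 0.58), -0.43 for G6pc (SE 0.65) and -0.51 for Cyp8b1 (SE 0.24). For GW4064 by knockdown under glucagon 0 genes passed in either fit, with 814 at an unadjusted p under 0.05, and Pck1 at 0.33 (SE 0.83), Fbp1 at 0.30 (SE 0.55) and Nr0b2 at 0.20 (SE 0.23). The interaction of all 3 factors also passed for 0 genes in either fit (709 at an unadjusted p under 0.05), with Ppargc1a at -0.96 (SE 1.1) and G6pc at 0.57 (SE 0.92). No list was called in these 3 tests. Averaged over the hairpins, Osgin1 differed by 0.51 under insulin and 1.13 under glucagon, and the interaction of 0.62 had an adjusted p of 1.00, and 0.539 with the block.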

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

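The tests of the probe sets below were chosen after the data had been seen. Probe sets without a symbol or with several were outside the gene tests and were tested over all probe sets, where signal above the threshold is a signal in data the comparisons did not use. For glucagon against insulin in control cells with DMSO, 157 probe sets without a symbol and 49 with several passed. In FOXA2 shRNA cells 122 and 50 passed. In the average of 4 conditions 661 without a symbol passed (333 higher, 328 lower) and 209 with several (83 higher, 126 lower). These were 4.13% of the 16010 probe sets without a symbol and 11.5% of the 1814 with several, against 13.8% of those with 1 symbol.

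For the knockdown averaged over 4 conditions 1 probe set without a symbol passed, 17352016, at -1.07 (adjusted p = 4.2e-04), with -1.01, -0.78 and -1.43 in experiments 1 to 3. Its level went from 5.54 with shlacZ to 4.54 with shFOXA2 under insulin and DMSO, from 6.28 to 4.37 under insulin and GW4064 and from 5.80 to 4.48 under glucagon and GW4064. Under glucagon and DMSO it was 4.80 and 4.75, with a difference of 0.70 in experiment 2. For GW4064 averaged over 4 conditions 1 probe set with several symbols passed, 17528249, at 1.89 (adjusted p = 3.0e-05), with 2.05, 1.89 and 1.71. It carries the FXR target of the core set that was left out together with another gene, so its signal cannot be assigned to either. Under glucagon it differed by 2.47 in control cells (adjusted p = 0.0200) and by 2.56 in FOXA2 shRNA cells (adjusted p = 0.0125), the largest GW4064 differences that passed within a single condition. Its level in control cells was 3.35 under insulin and 3.71 under glucagon with DMSO, and 4.55 and 6.18 with GW4064. The DMSO levels lay close to the floor, so these differences are set against near-background signal. Under insulin it did not pass, and its interaction with the hormone in control cells, 1.27, had an adjusted p of 1.00. For the knockdown under insulin and DMSO, probe set 17210203, without a symbol, was at -0.80 (adjusted p = 0.00854). No explanation was tested for these probe sets.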

How the results depend on the processing

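The block combined with a left-out array or experiment, with the filter on dim genes or with all probe sets was chosen after the data had been seen, and the other alternatives were planned. In none of them did a gene named by the rule, passing in the main fit or in the alternative, change sign. With quantile normalization or centring, 0 called lists had a median that changed sign. Medians of lists not called did change sign, for 11 of the 20 lists with GW4064 in control cells under insulin and 7 with averaged GW4064. Signal near the floor of the arrays limits what can be said of Nr0b2, Cyp7a1, Cyp8b1, and Pck1, G6pc, Nr4a3 and Ppargc1a under insulin. Leaving out arrays lowers the number of samples. Each experiment left out removed as many arrays but gave unlike counts for glucagon, so that number alone does not account for them. For the other changes below the cause was not tested. Foxa2 differed with the averaged knockdown by -0.59 to -0.32 over 38 alternatives, with adjusted p from 0.00730 to 1.00 and under 0.05 in 12.

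With the replicate block, glucagon changed 2481 genes in control and 2500 in FOXA2 shRNA cells with DMSO and 5454 in the average. It kept all of the 1039, 1062 and 3600 called without it. GW4064 changed 1 gene under glucagon in control cells and 1 in FOXA2 shRNA cells, and the knockdown 0 under insulin and 17 in the average, with Foxa2 at -0.43 passing. List tests called 42 lists over all comparisons instead of 20, and with an estimated correlation 17 instead of 14. Of 132 calls of named genes 131 were kept, Csnk2a1 under insulin was lost and 6 were gained. The block changed no other call of a gene named by the rule, and Osgin1 with GW4064, named after its values were seen, was gained.

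With quantile normalization the averaged knockdown changed 4 genes, with Foxa2 at -0.47, with arrays centred on their medians 4, with Foxa2 at -0.44, and with array weights 4, with Foxa2 at -0.47. The knockdown under insulin changed 0 genes with the dimmest 30% of genes left out, 0 with eBayes trend and robust settings and 0 with only the arrays of the compared groups. The last fit, on fewer arrays, gave 541 and 409 genes for glucagon in control and FOXA2 shRNA cells. With all probe sets, each of several symbols counted as well, GW4064 changed 1 in control and 1 in FOXA2 shRNA cells under glucagon and 1 in the average, and the knockdown 2 under insulin. The 1 in the average was probe set 17528249, of several symbols, and the calls of Mybl1 and Nr0b2 were lost (adjusted p = 0.0577 and 0.0659). Over all alternatives these 2 passed in 18 and 14 of 38.

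With the block and the glucagon and DMSO array of FOXA2 shRNA cells in experiment 3 left out, glucagon changed 2778 genes in control cells, 2001 in FOXA2 shRNA cells and 5596 in the average. GW4064 changed 2 and 2 under glucagon, 1 in FOXA2 shRNA cells under insulin and 5 in the average, the knockdown 0 under insulin and 10 in the average (Foxa2 -0.45), and hormone by knockdown gave 1. With the block and the dimmest 30% left out the counts were 2603, 2633 and 5555 for glucagon, 1 and 1 for GW4064 under glucagon, and 0 under insulin and 17 in the average for the knockdown (Foxa2 -0.43). With the block and all probe sets they were 2532, 2419 and 6475 for glucagon, 2 and 2 for GW4064 under glucagon, 8 for the averaged knockdown and 2 for hormone by knockdown, and for averaged GW4064 Mybl1 was kept (adjusted p = 3.3e-04) and Nr0b2 lost (0.0883).

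Leaving out 1 array or experiment at a time, the counts ranged from 297 to 982 for glucagon in control cells, 362 to 913 in FOXA2 shRNA cells and 2018 to 3685 in the average. They ranged from 0 to 0 for the knockdown under insulin, 0 to 4 for its average (Foxa2 -0.59 to -0.32) and 0 to 3 for averaged GW4064. Leaving out 1 experiment, list calls ranged from 23 to 30. Foxa2 also passed without the experiment 3 array of shlacZ under glucagon with DMSO (adjusted p = 0.0283) or GW4064 (0.0413). The same held without that of shFOXA2 under insulin with DMSO (0.0132) or GW4064 (0.0279), or under glucagon with DMSO (0.0448). Foxa2 did not pass with any other single array left out. The averaged GW4064 count changed without 19 of the 24 arrays, to 1 without the experiment 1 array of shlacZ with glucagon and DMSO or the experiment 3 array of shFOXA2 with glucagon and GW4064, and to 0 without the other 17. It stayed at 2 without the experiment 2 or 3 array of shFOXA2 with insulin and DMSO, the experiment 2 array of shFOXA2 with insulin and GW4064, or the experiment 3 array of shlacZ with GW4064 under either hormone. The averaged knockdown count was 4 without the experiment 1 array of shlacZ with glucagon and GW4064 or the experiment 3 array of shFOXA2 with insulin and GW4064. It was 1 without 9 others, those of experiments 1 and 2 of shlacZ with insulin and GW4064, experiment 2 of shlacZ with glucagon and GW4064, experiment 2 of shFOXA2 with insulin and DMSO, experiment 1 of shFOXA2 with insulin and GW4064, experiments 1 and 2 of shFOXA2 with glucagon and DMSO, and experiments 1 and 3 of shFOXA2 with glucagon and GW4064.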

Other observations

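The lists of NRF2 and NF-kB targets, the gene families, the Foxa2 pair differences for swapped hairpin labels, the GW4064 pairs of left-out experiments and the comparison of Foxa2 across hairpins were tests chosen only after the result was seen. Genes for RNA helicases of the DEAD box family were lower under glucagon averaged over 4 conditions. Of 31 Ddx genes 0 rose, 17 fell and 14 did not pass, against 3.87 falls expected (hypergeometric adjusted p = 3.0e-06 over 157 families, genes not being independent), and 14 fell with quantile normalization and 17 with arrays centred on their medians. The median was -0.20, at -0.18, -0.22 and -0.19 in experiments 1 to 3, with Ddx31 at -0.54 and Ddx52 at -0.48. Of 10 Utp genes, for processing of ribosomal RNA, 6 fell and 4 did not pass (median -0.18, adjusted p = 0.0263). Of 331 Zfp zinc finger genes 72 fell, 33 rose and 226 did not pass (median -0.04, adjusted p = 1.0e-04), among them Zfp36, which marks inflammatory transcripts for decay, at -1.62. Of 12 Pik genes 7 rose, 1 fell and 4 did not pass (median 0.26, adjusted p = 0.00945), and Pik3r1, a regulatory subunit of the insulin-signalling kinase, rose by 0.56. Expected counts for the families were taken over 15526 genes without regard to level. Whether expression level accounts for the excesses was not tested.

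NF-kB targets moved with glucagon in a way that differed between experiments. Averaged over 4 conditions, 2 of 10 rose and 5 fell, with a median of -0.95 (camera p = 0.0130, with an estimated correlation 0.376), at -1.55, -1.22 and 0.10 in experiments 1 to 3. In FOXA2 shRNA cells with DMSO 5 fell (median -1.51, camera p = 2.5e-05, with an estimated correlation 0.142), at -1.52, -1.35 and -1.56. In experiment 3 this difference rests on an insulin array with an NF-kB target median of 8.44, against 6.63 to 7.07 on the other 3 insulin arrays of the experiment, and on the glucagon array described below. In control cells with DMSO the experiments gave -1.49, -1.08 and 0.81. NRF2 targets had a median of 0.24 in the average, with 3 rises among 9 (camera p = 9.1e-04, with an estimated correlation 0.197).

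Few genes changed with the FOXA2 hairpin. A weak knockdown in experiment 3 was weighed as a cause, since Foxa2 was at -0.12 there. Without that experiment 1 gene passed instead of 2, and 8 instead of 17 with the block, but fewer arrays also lower the count. Without experiment 1 or experiment 2, on as many arrays, 0 genes passed in either fit. The counts therefore do not decide whether the weak knockdown kept the number low. The 1 gene that passed without experiment 3 was Foxa2 (adjusted p = 0.00805), and Csnk2a1 and Uxs1 no longer passed (0.105 each). Swapped hairpin labels were weighed as well. Foxa2 was lower on the shFOXA2 array in 12 of 12 pairs. In experiments 1 and 2 the smallest difference was -0.420, against an SD of 0.133 between pairs of an experiment, which argues against swaps within those pairs. In experiment 3 it was -0.0347, within that SD, so a swap there stays open. Whether a knockdown of 25.9% at the transcript level is too small to change many FOXA2 targets was not tested.

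Osgin1 and Mybl1 were higher with GW4064 in 12 of 12 pairs each, but genes picked for their rise do not test it. Each also passed with the block in any 2 experiments and was then higher in 4 of 4 pairs of the experiment left out, 12 of 12 in all, with means of 0.83, 0.91 and 0.72 for Osgin1 (SE 0.20, 0.26 and 0.16), which argues against 1 experiment or a few arrays as the source. Of the 6 other genes that passed without experiment 3, 3 moved the same way in 4 of 4 of its pairs, Nr0b2 and Gcnt2 in 3 and 1700010D01Rik in 0. An oxidative stress response through NRF2 would raise its targets, whose median was 0.00076, which argues against it. By experiment the NRF2 target median was -0.0029, -0.0782 and 0.00975. The 95% interval of the mean over 12 pairs was -0.0740 to 0.0183, with a camera p of 0.644. That interval takes the 4 pairs of an experiment as independent, so it may be too narrow. An FXR response may be the cause. The FXR targets other than Osgin1 had a median of 0.0653, with a camera p of 0.0127, 3.3e-04 with the block and 0.0624 with an estimated correlation. The highest of them was Nr0b2, at 0.53, which passed singly in limma. The 95% interval of the mean of the list median over the 12 pairs was -0.0205 to 0.142, the pairs again taken as independent. That interval spans both 0 and a rise. Outside these 12 targets, a probe set that carries a left-out FXR target together with another gene, 17528249, rose by 1.89 with GW4064. It was at 2.05, 1.89 and 1.71 in experiments 1 to 3, from DMSO levels close to the floor. Its signal cannot be assigned to either gene, so an FXR response as the explanation stays open.

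The glucagon and DMSO array with the FOXA2 hairpin of experiment 3 had an NF-kB target median of 6.33, against 7.23 to 8.49 on the other 3 glucagon arrays of the experiment. In experiments 1 and 2 the glucagon arrays lay between 6.16 and 6.72, so the other 3 stand apart from those and this array does not. Fewer macrophages were weighed, and the macrophage marker median differed by -0.0226. Of the 10 markers 8 had a mean under 3.25, near the floor, where a loss would not be seen, so this explanation stays open. An effect of the knockdown under glucagon would recur, but the difference was 0.29 and 0.20 in experiments 1 and 2 and -1.64 in experiment 3. An insulin array under a glucagon label would have low Pck1, which was 9.75 here, 3.07 to 4.16 on insulin arrays and 8.01 to 10.7 on the other glucagon arrays. What set the other 3 arrays apart was not tested.

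The Foxa2 level with the hairpin under glucagon lay 0.76 above that of control cells under insulin, in 3 of 3 experiments. Without cells that had neither hormone, a rise by glucagon and a fall by insulin cannot be told apart. A weaker hormone response with the hairpin was tested on the GW4064 arrays, over the genes called on the control arrays with DMSO. The ratio of the responses was 1.01 on average (SD 0.033), at 0.999, 0.991 and 1.05 in experiments 1 to 3. The 95% interval of the mean was 0.933 to 1.09, which argues against a ratio under 0.9.

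Other splits of the same arrays into groups were fitted in the same way. For the comparisons of 3 arrays with 3, the 10 splits are too few for a share under 0.05. For glucagon against insulin the real counts were 1039 in control cells and 1062 in FOXA2 shRNA cells, and the highest of the other splits 0 and 1, so 1 of 10 splits gave as many genes. For GW4064 the real count was 0 in all 4 conditions and the highest other 0, 0, 0 and 1, so 10 of 10 splits gave as many, which a real count of 0 makes certain. For the knockdown the real count was 1 under insulin and the highest other 0 (1 of 10 splits), and 0 under glucagon with a highest other of 0 (10 of 10).

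For the averages over 4 conditions 100 splits were drawn, with the pairs of an experiment exchanged as if independent. The real count and the highest other were 2 and 1 for the knockdown, 2 and 0 for GW4064 and 3600 and 2393 for glucagon, with 1 of 100 splits as large in each case. For glucagon this share argues against chance, with the pairs taken as independent. The counts of 2 are small and unstable, and both fell to 0 without experiment 1 or experiment 2, and that for GW4064 also without any 1 of 17 arrays. The splits therefore do not exclude chance for the knockdown or for GW4064. For the interactions the real count was 0, so 100 of 100 splits were as large whatever the data, and the splits say nothing of them. The highest other was 1962 for GW4064 by hormone in control cells, 1 for GW4064 by knockdown under glucagon, 2117 for hormone by knockdown and 1 for all 3 factors. The counts of 2393, 1962 and 2117 point to a structure of the samples, the hormone. Between the 2 sides of these splits the share of glucagon arrays differed by 83.3%, 100% and 100% of the arrays of a side, and splits with equal shares (25, 50 and 38 of 99) gave 0 genes.

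The first 4 principal components of the arrays held 33.3%, 20.5%, 10.3% and 4.00% of the variance. The first parted the hormones, the second set experiment 3 apart and the third experiment 1. The fourth was carried by the glucagon and DMSO array of FOXA2 shRNA cells of experiment 3, with a score of 27.4 against -13.4 to 5.79 on the others. That array also had the lowest array weight, 0.510, the next being 0.694.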
